A study of Mus musculus with 2 samples.

How the data were processed

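The series holds 2 single-cell RNA libraries, each from the liver of 1 mouse. The control mouse was given a GFP virus. The other was given a Cre virus to induce loss of glutamine synthetase (GS_KO). Per the labels, both mice were 11 weeks old, carried floxed Glul alleles and no tumours, and were sampled 2 weeks after the virus was given. Livers were perfused with collagenase II at 0.3 mg/mL, the cells were filtered and spun at low speed, and hepatocytes were combined with purified non-parenchymal cells. The labels name a 10x Genomics 5-prime library of version 3 and an Illumina NextSeq 2000 run. They call the assay both single-cell and single-nucleus sequencing, so whether whole cells or nuclei entered the droplets is left open here.

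The authors deposited 1 matrix of UMI counts per library, with 32285 mouse genes, and counting was done with Cell Ranger 8.0.0 per the file headers, on the mm10 build per the submitters' processing notes. The counts are whole numbers per gene and barcode and are not normalized. How barcodes were selected for deposit is not given in the sources used here. The lowest barcode held 119 UMIs in the control matrix and 123 in the GS_KO matrix, so no barcode under 100 UMIs is held. Gene names and identifiers were used as the files give them. The position of Glul was taken from the GENCODE annotation of the same build.

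A barcode was taken as a cell when it held at least 1000 UMIs and at most 30% mitochondrial UMIs. This left 1703 control and 1834 GS_KO barcodes, and the mitochondrial limit removed none of them. Scrublet, as implemented in scanpy 1.11.5 with an expected rate of 6%, called 2 control and 8 GS_KO barcodes as doublets, and these were removed. That is 0.117% and 0.436% of barcodes. At a minimum of 500 UMIs it called 0.00730% of 13691 control barcodes and 0.0168% of 11871 GS_KO barcodes, and both settings lie too far under the expected rate for it to have worked, so doublets are in effect untreated. Cells of both libraries were clustered together on 2000 variable genes, chosen by the variance of Pearson residuals (theta 100) ranked in each library. Values were scaled to 1000 UMIs per cell, log-transformed and centred within each library, and 30 principal components, 15 neighbours and the Leiden method at resolution 1.0 were used (igraph 0.11.9, seed 1, 10 iterations). Clusters were named from 195 markers of 18 cell classes. For classes other than hepatocytes, at least 3 markers had to be 2-fold or more above the other cells with at least 5 UMIs each, at least 1 of them among the 50 leading genes, and the class with the largest summed log2 excess was taken. A cluster that met this for no class was named hepatocyte when at least 3 hepatocyte markers lay over 3 standard deviations above the free RNA allowed for its barcodes, and was left unnamed otherwise. A named cluster of at least 40 cells whose 10 leading genes held more markers of another class than of its own was divided once at resolution 1.0 and its parts were named again. A cluster that still failed this was left unnamed. All class names are short for "like": a hepatocyte here is a cell of a hepatocyte-like cluster. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, anndata 0.12.19 and matplotlib 3.10.9.

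Counts were summed over the cells of a class in each library and scaled to CPM (counts per 1000000) of the class total. Ratios are GS_KO over control on a log2 scale, with 0.5 counts added to each sum. Each group is 1 library of 1 mouse, so no test between conditions was possible and no p-value is given. An interval in the text is an exact 95% Poisson interval for a level, the matching conditional interval for a ratio, a Poisson resampling of the sums (1000 draws) for the median of a list, and an exact binomial (Clopper-Pearson) interval for a share. All of these cover counting error only and not the difference between mice, digestions or library preparations. A gene at 0 counts in a library was set to 3 counts to give a lower bound on its fold. Gene lists (40, of which 4 are name patterns and the rest hold 481 named genes, 3 of them not among the gene names in the files) were compared over members with at least 20 UMIs in both libraries together, in classes of at least 100 cells per library. For each list in hepatocytes and Kupffer cells the median log2 ratio is given with its percentile among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries.

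Genes were named by a fixed rule. Candidates had at least 50 CPM in either library and at least 100 UMIs in the class, and were ranked on the log2 ratio of CPM with 5 CPM added. The 15 highest and 15 lowest were taken in hepatocytes and in Kupffer cells, and 5 of each in other classes of at least 200 cells per library. Mitochondrial, ribosomal protein, immunoglobulin, T cell receptor, clone-named and sex-linked check genes were left out, and so were genes likely to have leaked from another class. In classes other than hepatocytes these were genes with over 5 times the class level in hepatocytes, and in hepatocytes genes with over 5 times the hepatocyte level in another class of at least 50 cells, in the library with the higher value. From a list, the 2 highest and 2 lowest members with at least 100 UMIs were taken. Glul is always given, and any further gene was chosen after its values were seen.

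Other settings tried were minimums of 500 and 2000 UMIs per cell, a mitochondrial limit of 15% or none, doublets kept, Leiden resolutions of 0.5 and 2.0, scaling by the median of ratios in place of the class total, the mean of per-cell CPM in place of the sum, and 5 or 100 UMIs for a list member. The control matrix held 61635695 UMIs with a median of 352 per barcode and the GS_KO matrix 57973740 with a median of 304, and the hepatocyte sums used here held 1994342 and 2138526 UMIs.

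The groups, the minimums of UMIs per cell and per list member, the mitochondrial limit, the clustering resolution, the markers, the gene lists, the rule for named genes and most of the other settings tried were fixed before the data were examined. Other choices were made afterwards. Several versions of the choice of variable genes, the centring by library and the rules for naming and dividing clusters were tried, and they were judged on how well classes could be named. A minimum of 500 genes per cell was used at first, was in no plan, and was dropped after its classes had been seen; it is kept as an alternative. The planned profile of free RNA from barcodes under 100 UMIs could not be made and was replaced by that of barcodes of 200 to under 300 UMIs. Its share of a class was estimated in 2 ways. The first used genes of another class: Alb, Ttr, Apoa1, Apoc3, Fgb and Serpina1c for classes other than hepatocytes, and Kupffer, LSEC and stellate markers for hepatocytes. The second took the median UMIs of all barcodes in a library as the free RNA of each cell. Readouts over barcodes of 200 to under 400 UMIs and over all barcodes, and a clustering without 421 genes (the leading genes of the Kupffer clusters, the MHC class II list and immunoglobulin genes), were also added after seeing the data, as was a reading of the Kupffer markers in each library. The planned cell calling at 10% of the 99th percentile of the 10000 largest barcodes set limits of 184 and 206 UMIs and would have taken 160362 and 162666 barcodes as cells, so it was not run.

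The steps after the class sums were tested on simulated Poisson counts drawn from the pooled gene proportions of a class at the real library totals, with 200 genes changed by known folds, 50 for each size. Over the 9730 genes measured in hepatocytes, 90% of the genes changed 1.5-fold, 98% of those changed 2-fold and 100% of those changed 4-fold or 8-fold had the right direction, and the intervals held the true value for 94%, 98%, 94% and 98% of these genes. Over the 2334 genes measured in Kupffer cells, the right direction was found for 78% at 1.5-fold and 94% at 2-fold. Over the 8065 genes measured in Kupffer cells at a minimum of 500 UMIs, it was found for 78% and 98%. A simulated hepatocyte list of 20 genes lowered 1.5-fold fell below all random lists, and one of 20 unchanged genes lay at the 8.13th percentile. The simulated counts follow the model that the intervals assume, with no free RNA, no clustering and few changed genes. They check the calculation and do not show how well changes are resolved in the real libraries.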

Results

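The libraries come from the livers of 2 male mice, 1 control given a GFP virus and 1 with Glul deleted by a Cre virus. The male-linked transcript Ddx3y stood at 56.9 CPM in the control library and 51.2 CPM in the GS_KO library, and Xist at 0.0811 and 0.0172 CPM. The control matrix held 166037 barcodes with a median of 352 UMIs (middle range 304 to 400), and the GS_KO matrix 175937 with a median of 304 (264 to 346). Barcodes of at least 1000 UMIs, the ones read as cells here, numbered 1703 and 1834, or 1.03% and 1.04% of barcodes, and held 3.54% and 4.21% of UMIs. The nuclear transcript Malat1 was higher in larger barcodes: 1685 CPM at 300 to 400 UMIs and 18713 CPM at 1000 to 1500 UMIs in the control library, and 1504 and 36254 CPM in the GS_KO library. The median mitochondrial share was lower in the larger of these barcodes, at 8.88% and 3.32% in the control library and 8.08% and 2.32% in the GS_KO library. The labels state a minimum of 10000 cells, and 13692 and 11871 barcodes held at least 500 UMIs.

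**Figure D1:**
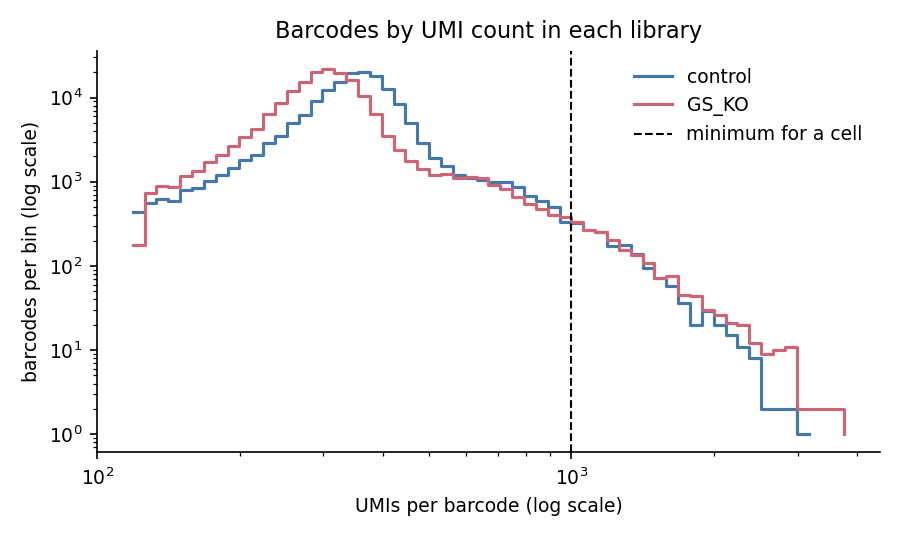
Barcodes by UMIs per barcode in the control and GS_KO libraries, with a dashed line at 1000 UMIs. Medians are 352 and 304 UMIs, and 1703 and 1834 barcodes lie at or above the line.

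Most cells clustered as hepatocytes. They numbered 1564 in the control library and 1609 in the GS_KO library, beside 30 and 131 Kupffer cells, 102 and 71 stellate cells or fibroblasts, and 5 and 15 plasma cells. At Leiden resolution 2.0 an LSEC cluster of 19 and 12 cells stood apart, with 79 and 58 stellate cells and 1568 and 1610 hepatocytes. The class named stellate here is therefore likely to hold LSECs too. Hepatocyte RNA was present in every class: the median of 12 hepatocyte markers stood at 83.9% of its hepatocyte level in control Kupffer cells and 77.2% in GS_KO Kupffer cells, and at 85.0% and 95.2% in stellate cells. Values in those classes therefore mix their own RNA with hepatocyte RNA. Hepatocyte clusters were shared unevenly between the libraries although each library was centred on its own mean. The cluster led by Tox, Tenm3 and Cyp7a1 held 641 control and 101 GS_KO cells, and the cluster with Slc1a2, Lgr5 and Glul, genes of the hepatocytes next to the central vein, held 88 and 23. The cluster with Cyp2c39 and Cyp2c29 held 16 and 543 cells, that with Hal and Hsd17b6 held 11 and 288, and that with Csf1, Birc3, Relb and Icam1 held 2 and 283.

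Glul, the deleted gene, was lower in GS_KO hepatocytes. It stood at 123 CPM (95% interval 108 to 140) in the control library and 29.5 CPM (22.6 to 37.7) in the GS_KO library, a log2 ratio of -2.06 (-2.49 to -1.66), or 4.19-fold lower (3.16 to 5.61). This and all later intervals cover counting error only. When hepatocytes were ranked within each library on pericentral genes other than Glul, Glul in the control library ran from 73.5 CPM (49.2 to 106) in the lowest 20% of cells to 233 CPM (188 to 286) in the highest, and in the GS_KO library from 17.2 CPM (6.93 to 35.5) to 52.4 CPM (33.2 to 78.7). These groups are not matched between the libraries: the mean pericentral score of the highest was 0.321 in the control and 0.212 in the GS_KO library. The Glul difference was larger in barcodes of 200 to under 400 UMIs, at 113 and 9.78 CPM (11.6-fold lower, 10.5 to 12.8), and over all barcodes, at 114 and 13.9 CPM (8.16-fold, 7.59 to 8.79). It was smaller with free RNA taken off with its share set by marker genes of other cell classes (by markers below), at a log2 ratio of -1.63, and at a minimum of 2000 UMIs per cell, which left 19 and 33 hepatocytes, at -0.91. Over all barcodes of at least 2000 UMIs Glul had 9 and 11 UMIs, or 63.7 and 39.2 CPM, and the interval of its log2 ratio, -2.11 to 0.75, reached 0. With each cell thinned to 1000 UMIs, a Glul UMI was found in 9.78% of control and 2.67% of GS_KO hepatocytes. The matching shares were 13.3% and 4.58% of Kupffer cells and 11.8% and 2.82% of stellate cells. In the control library barcodes of 200 to under 400 UMIs held 113 CPM, so single cells positive for Glul are not separated from background there. In the GS_KO library those barcodes held 9.78 CPM, under the 29.5 CPM of hepatocytes. Free RNA at that level would not account for all Glul in GS_KO hepatocytes. Glul counts in Kupffer cells were 4 and 11 UMIs, a 1.65-fold difference with an interval of 0.384 to 5.58. At a minimum of 500 UMIs they were 36 and 89 UMIs, or 121 and 79.5 CPM (1.52-fold lower, 1.00 to 2.26). The labels do not name the deleted exons and a 5-prime read can begin upstream of them, so these counts do not separate deleted from intact transcript and are a limited check of the deletion.

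**Figure D2:**
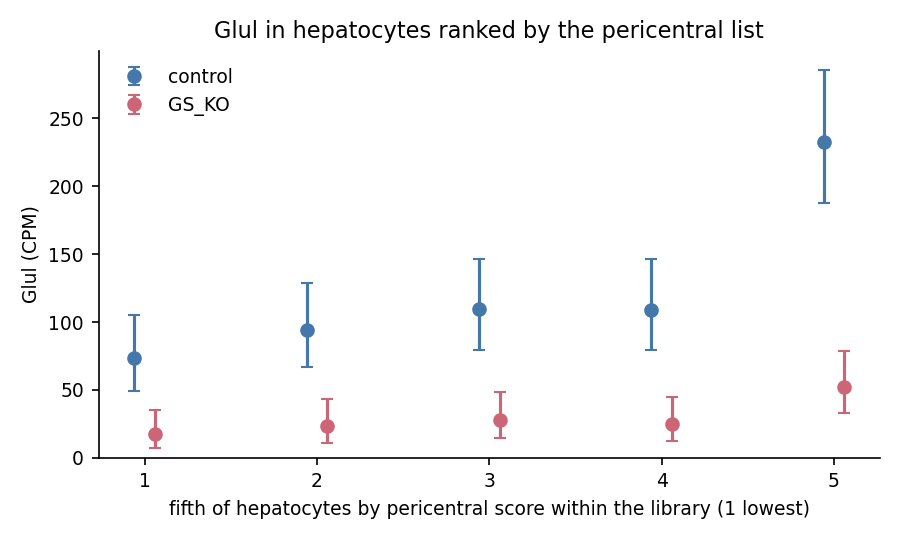
Glul CPM in 5 equal groups of hepatocytes ranked on pericentral genes within each library, with exact 95% Poisson bars. The highest group holds 233 CPM in the control library and 52.4 CPM in the GS_KO library. Groups are not matched between libraries: the mean pericentral score of the highest is 0.321 and 0.212.

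Genes of the pericentral zone were lower in GS_KO hepatocytes. The pericentral list had a median log2 ratio of -0.74 (-0.90 to -0.54), with 20 of 21 measured members lower, and lay below all 10000 matched random lists. Oat, which makes glutamate from ornithine, stood at 263 CPM in the control and 35.1 CPM in the GS_KO library (-2.90, -3.27 to -2.55). Slc1a2, a glutamate transporter, stood at 373 and 65.5 CPM (-2.50, -2.78 to -2.25). Cyp2e1 stood at 5607 and 2429 CPM (-1.21, -1.25 to -1.16), and Lgr5, an R-spondin receptor, differed less, at 80.2 and 64.1 CPM (-0.32), as did Lect2 (-0.29). Beta-catenin target genes had a median of -0.99, with 0 of 13 higher (below all random lists), and Axin2 at -0.99. The periportal list had a median of -0.35 (-0.41 to -0.19), with 9 members higher and 11 lower, and lay within the central 95% of random lists (-0.378 to 0.309; percentile 3.85). Its median was -0.0807 with free RNA taken off by markers and -1.15 at 2000 UMIs, so it is not read as lower. Its ends lay far apart: Hal, which degrades histidine, stood at 96.8 and 441 CPM (2.19, 1.96 to 2.42) and Hsd17b6 at 27.6 and 174 CPM (2.65), but Mfsd2a at 192 and 7.48 CPM (-4.64) and Etnppl at 65.7 and 3.74 CPM (-4.05). The pericentral median turned to 0.12 when free RNA was taken off by markers, which left hepatocyte markers at 4.54% and 26.4% of their hepatocyte level. It stayed at -0.58 with the share set by the median UMIs of all barcodes, and was -0.74 (2 higher, 20 lower) with the first correction at a minimum of 500 UMIs per cell.

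Glutamine and glutamate genes were mostly lower in GS_KO hepatocytes, with a median of -0.48 (-0.62 to -0.37), 5 members higher and 18 lower, at percentile 0.245. Glud1, which links glutamate to the citric acid cycle, lay at -0.91. Gclc, the first enzyme of glutathione synthesis, stood at 194 and 454 CPM (1.23, 1.06 to 1.40), and Gfpt1, which uses glutamine to make hexosamine, at 23.1 and 38.8 CPM (0.74, 0.21 to 1.30), but Gclc lay at -0.13 in barcodes of 200 to under 400 UMIs. Urea cycle genes, the other route of ammonia disposal, had a median of -0.91 (2 higher, 8 lower; percentile 0.0700). Cps1, the entry enzyme, stood at 9328 and 3111 CPM (-1.58, -1.62 to -1.54) and Asl at 396 and 146 CPM (-1.43), while Nags lay at 0.34 and Otc at 0.15 (-0.14 at a minimum of 500 UMIs). Cps1 differed less in barcodes of 200 to under 400 UMIs, at 2530 and 2073 CPM (-0.29). The amino acid response list had a median of 0.43 with 4 members higher and 4 lower (percentile 94.6), with Atf3 at 56.2 and 144 CPM (1.35), Atf5 at 1.21, Got1 at -1.21 and Cebpb at 324 and 236 CPM (-0.46). In barcodes of 200 to under 400 UMIs that median was -0.16 and Atf3 lay at -0.23, and Cebpb lay at 1.25 with free RNA taken off by markers.

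Among sterol and lipid lists, cholesterol synthesis genes were higher in the GS_KO library (median 0.95; 16 higher, 3 lower; above all random lists), with Hmgcs1 at 55.7 and 283 CPM (2.34, 2.05 to 2.65) and Sc5d at 138 and 522 CPM (1.91), but Stard4 at -0.81. Bile acid genes had a median of 0.05 (9 higher, 7 lower; percentile 74.8), and -0.34 in barcodes of 200 to under 400 UMIs. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, stood at 1154 and 147 CPM (-2.97, -3.14 to -2.80), and the bile salt exporter Abcb11 at 154 and 839 CPM (2.44) and Nr0b2, a repressor of Cyp7a1, at 54.2 and 372 CPM (2.78). Fatty acid oxidation genes were lower (median -0.59, 6 higher, 12 lower, percentile 0.0300). Cyp4a10 stood at 123 and 1.40 CPM (-6.23, -8.74 to -4.89), with no control count left when free RNA was taken off by markers. Fasting genes had a median of -0.38 (3 higher, 8 lower, percentile 10.5). Igfbp1 at 153 and 509 CPM and G6pc at 666 and 1112 CPM were among the 3 higher members. Lipogenesis genes had a median of -0.38 (6 higher, 10 lower; percentile 4.26): Thrsp stood at 1406 and 212 CPM (-2.73) and Scd1 at 277 and 612 CPM (1.14; -0.0682 with free RNA taken off by markers). The lipogenesis median was 0.03 at a minimum of 500 UMIs per cell, 0.46 in barcodes of 200 to under 400 UMIs and 0.32 over all barcodes. The fatty acid oxidation median was 1.52 with free RNA taken off by genes of other classes, but -0.56 with that correction at 500 UMIs. The same correction moved the medians of lipogenesis to -0.79, cholesterol synthesis to 1.51 and amino acid response to 1.52.

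Xenobiotic genes had a median of -0.42 in hepatocytes (5 higher, 12 lower; percentile 2.04), with Alas1, the first enzyme of heme synthesis, at 2700 and 225 CPM (-3.58, -3.72 to -3.45), Cyp2b10 at 64.2 and 6.08 CPM and Cyp3a25 at 1204 and 6002 CPM (2.32). Nrf2 targets had a median of -0.27 (4 higher, 6 lower; percentile 13.1) with Osgin1 at 62.2 and 416 CPM (2.74), and glycolysis and hypoxia genes one of -0.33 (1 higher, 11 lower; percentile 5.15) with Pfkfb3 at 107 and 6.55 CPM (-3.99). The xenobiotic and Nrf2 medians were 0.18 and 1.54 at a minimum of 2000 UMIs per cell. Respiratory chain genes of the nucleus were lower in 73 of 73 cases (median -0.83; below all random lists), mitochondrial genome genes in 13 of 13 (-0.63; percentile 1.36), and genes matching the ribosomal name pattern in 80 of 84 (-0.59; below all). The nuclear transcript Malat1 stood higher in large GS_KO barcodes, as given above. With free RNA taken off by markers the respiratory chain median was -0.28 (5 higher, 8 lower) and the ribosomal median -0.35, while with the share set by the median UMIs of all barcodes they were -1.14 and -0.94. The ribosomal pattern also takes in Rps6ka3, a kinase, at 0.79 (-0.91 at a minimum of 2000 UMIs). p53 targets had a median of 0.54 (8 higher, 2 lower; percentile 98.5), with Gdf15 at 39.6 and 166 CPM (2.06). Major urinary protein genes had a median of -0.11 (8 higher, 8 lower; percentile 32.8), with Mup20 at 42.1 and 365 CPM (3.11). The major urinary protein median was -0.42 at a minimum of 500 UMIs (percentile 0.345), 0.29 at 2000 UMIs, 0.21 at a minimum of 500 genes, and 0.78 and 0.13 with free RNA taken off by markers and by the median UMIs of all barcodes. The glycolysis median was 0.01 in barcodes of 200 to under 400 UMIs.

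**Figure D3:**
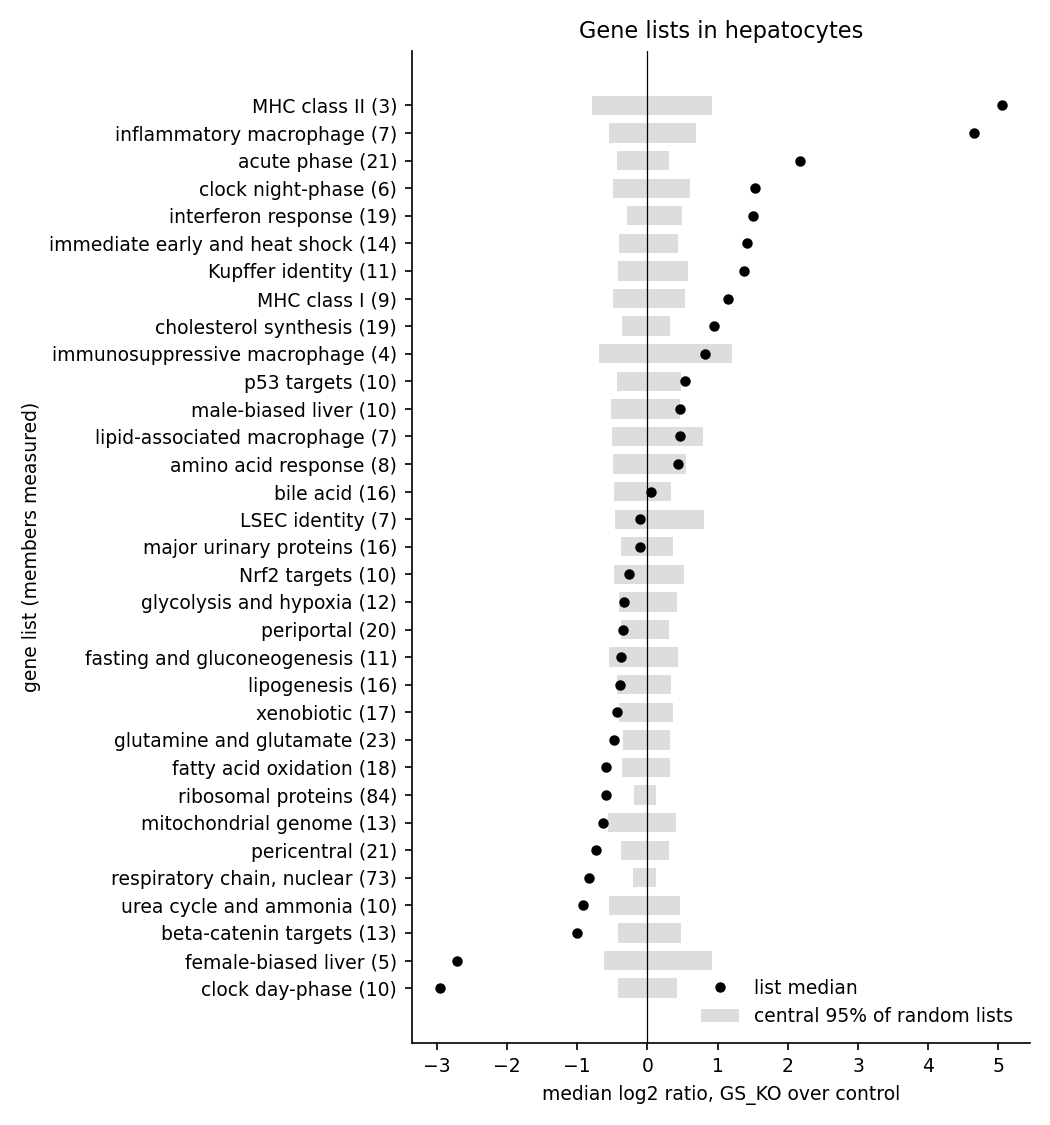
Median log2 ratio of 33 gene lists in hepatocytes, with the central 95% of matched random lists in grey. MHC class II lies highest at 5.04 and day-phase clock genes lowest at -2.95.

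Inflammatory and immune genes were higher in GS_KO hepatocytes. Acute phase genes had a median of 2.18 with 20 of 21 higher, interferon response genes one of 1.499 with 19 of 19 higher, both above all random lists, and MHC class I genes one of 1.15 with 9 of 9 higher (percentile 99.97). Lcn2, an iron-siderophore binding protein, stood at 8.52 and 1000 CPM (6.83, 6.19 to 7.66) and serum amyloid Saa2 at 9.03 and 585 CPM (5.98, 5.35 to 6.78), while Hamp, the iron hormone, stood at 3347 and 1597 CPM (-1.07). With free RNA taken off by markers Lcn2 lay at 4.44 and Hamp turned to 0.88. B2m, the MHC class I light chain, stood at 949 and 1050 CPM (0.15; -0.21 with free RNA set by the median UMIs of all barcodes). MHC class II had a median of 5.04 over 3 members (above all random lists), with Cd74 at 3.01 and 245 CPM (6.23) and H2-Aa at 2.51 and 89.3 CPM (5.02). The inflammatory macrophage list had a median of 4.65 with 7 of 7 higher (above all random lists; 3.67 with the member at 0 set to 3 counts), with the chemokine Cxcl1 at 83.7 and 727 CPM (3.11). Immediate early genes had a median of 1.42 (11 higher, 3 lower; above all), with Fos at 47.6 and 311 CPM and Btg2 at 38.6 and 434 CPM. Other lists of non-hepatocyte cells were read in these barcodes: Kupffer identity 1.38 (10 higher, 1 lower; above all), immunosuppressive macrophage 0.83 (3 and 1; percentile 91.95), lipid-associated macrophage 0.46 (5 and 2; 88.0) and LSEC identity -0.10 (3 and 4; 23.7), the last at 0.02 at a minimum of 500 UMIs. With free RNA taken off by markers, Kupffer identity lay at 0.13 over the 3 of 11 members left, a correction whose share is itself set on Kupffer markers among others, and interferon response genes lay at 2.87 (13 of 13 higher). The correction by markers left hepatocyte markers at 4.54% of their hepatocyte level in control and 26.4% in GS_KO hepatocytes. It therefore acted unevenly on the 2 libraries, and ratios after it, such as 2.87, are not read as sizes. Free RNA made up 52.3% of control and 38.5% of GS_KO hepatocyte UMIs as set by markers of other classes, and 27.6% and 22.9% as set by the median UMIs of all barcodes.

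Clock genes and female-biased genes also differed. Day-phase clock genes were lower in GS_KO hepatocytes (median -2.95; 1 higher, 9 lower; below all random lists) and night-phase genes higher (median 1.53; 5 higher, 1 lower; percentile 99.99). Arntl, a core activator of the clock, stood at 2.01 and 116 CPM (5.68, 4.47 to 7.73), and Dbp, one of its output genes, at 69.2 and 1.40 CPM (-5.41, -7.92 to -4.05; no control count left with free RNA taken off by markers). Usp2 stood at 88.8 and 0.468 CPM (-6.99, -12.88 to -5.07) and Npas2 at 0.501 and 70.1 CPM (6.55, 4.63 to 12.44), each with 1 UMI in the lower library. The labels give no time of day for the collections. Whether differences in the other lists and named genes go with the clock difference was not tested. Female-biased genes had a median of -2.71 with 0 of 5 higher (below all random lists) and male-biased genes one of 0.46 (7 higher, 3 lower; percentile 97.47), although both mice are male. Cux2, a female-biased transcription factor, had 504 UMIs in the control and 0 in the GS_KO library, at least 180-fold lower.

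Among the 3734 genes open to naming in hepatocytes, the 15 highest in the GS_KO library included 5 acute phase genes: Lcn2, Saa1 (35.6 and 1583 CPM), Saa2, Saa3 (5.52 and 298.8 CPM) and Orm2 (6.02 and 301 CPM). With free RNA taken off by markers, Saa1, Saa2, Saa3 and Orm2 had 0 UMIs left in both hepatocyte sums, and Saa1 and Saa2 stood higher in GS_KO barcodes of 200 to under 400 UMIs, at 5017 and 1793 CPM. With the share set by the median UMIs of all barcodes, Saa1 lay at 4.72, Saa2 at 5.18, Saa3 at 5.26 and Orm2 at 4.72. The correction by markers also took off most hepatocyte marker RNA, leaving it at 4.54% in control and 26.4% in GS_KO hepatocytes. The 0 counts it left therefore cannot tell whether hepatocytes hold these transcripts. How much of them is in hepatocyte cells stays open. Col4a3, a basement membrane collagen chain, had 0 UMIs in the control library and 299.3 CPM in the GS_KO library, at least 199-fold higher. Chrm3, a muscarinic receptor, stood at 21.1 and 747 CPM (5.13), Chka, a choline kinase, at 41.1 and 1014 CPM (4.62), and Ikbke, a kinase of innate immune signalling, at 5.52 and 159 CPM (4.78). The others were Lrmda (9.03 and 412 CPM), Pdzrn3 (3 UMIs in the control library and 150 CPM in the GS_KO library, 6.42, 5.08 to 8.93), Cybb (3 UMIs and 129 CPM, 6.20), Arntl, Mug2 (73.7 and 1264 CPM) and Rnf125 (23.6 and 442 CPM). Cybb stood higher in GS_KO barcodes of 200 to under 400 UMIs, at 206 CPM, so free RNA could bring part of it into hepatocyte barcodes. The 15 lowest included Fkbp5, a glucocorticoid-responsive gene, at 504 and 20.1 CPM (-4.63), Lpin1 at 1151 and 98.7 CPM (-3.54), Noct at 250 and 4.68 CPM (-5.67), Onecut1 at 415 and 20.1 CPM (-4.35), Tox at 699 and 70.1 CPM (-3.31), Homer2 at 271 and 24.8 CPM (-3.44), Aacs at 221 and 19.6 CPM (-3.47) and Sema3e at 91.3 and 5.61 CPM (-3.97), beside Cux2, Cyp4a10, Usp2, Mfsd2a, Alas1, Dbp and Pfkfb3.

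Macrophages made up a larger share of non-hepatocyte cells in the GS_KO library. Kupffer cells were 30 of 137 such cells (21.9%) in the control library and 131 of 217 (60.4%) in the GS_KO library, a difference of 38.5 points (28.0 to 47.8). The Kupffer cluster is led by MHC class II and C1q genes, which themselves differ between the libraries. Clustered without its leading genes, Kupffer cells were 26 of 130 and 112 of 206 (54.4%), 34.4 points apart, and at a minimum of 500 UMIs they were 27.7% (437 of 1577) and 67.0% (1603 of 2393). Clusters were named on both libraries together, so the 12 Kupffer markers were also read in each library. They stood at 3578 CPM in control and 5846 CPM in GS_KO Kupffer cells, against 202 and 242 CPM in hepatocytes, and at 7707 and 11091 CPM in Kupffer cells at 500 UMIs. At 2000 UMIs the 14 control cells of the cluster named Kupffer held 4 marker UMIs, all of Slc40a1, and the 46 GS_KO cells held 123 over 11 markers. The name does not hold for the control cells there, and no share is read at that minimum. Digestion, the low-speed spin and the mixing of hepatocytes with purified non-parenchymal cells also set these shares, and each was done for 1 mouse per group.

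**Figure D4:**
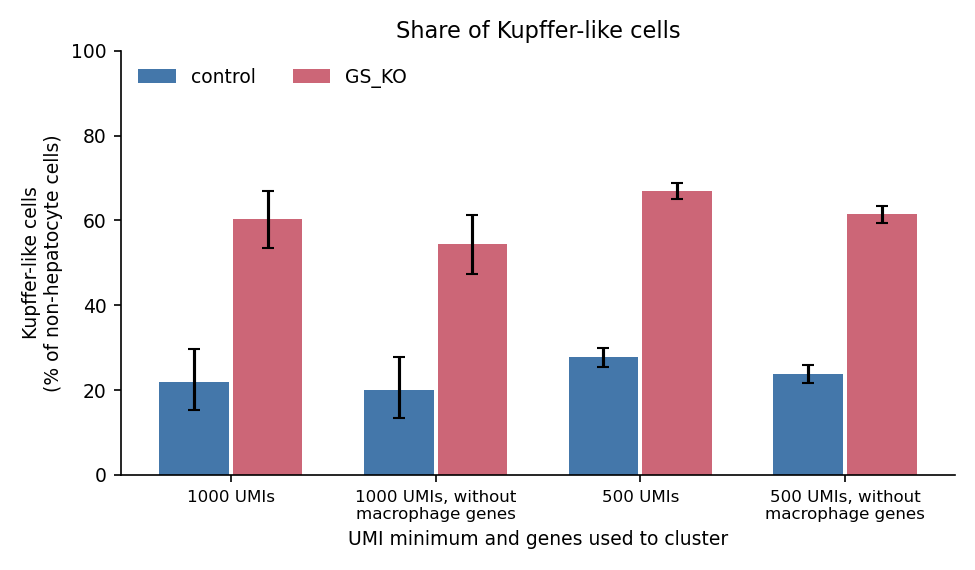
Kupffer cells as a percentage of named non-hepatocyte cells in the control and GS_KO libraries under 4 settings, with exact 95% binomial intervals. With the settings used throughout, the shares are 21.9% and 60.4%.

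The immunosuppressive macrophage list did not lie clearly to either side of 0 in Kupffer cells. Over 4 members its median was 0.20 (-0.45 to 1.28), 2 higher and 2 lower, with 30 control cells, under the minimum of 100 cells set for lists, and it was -0.19 with members taken from 5 UMIs. At a minimum of 500 UMIs, with 437 and 1603 Kupffer cells, the median was 0.16 over 12 members (7 higher, 5 lower; percentile 80.2), 0.38 with median of ratios scaling and -0.26 with free RNA taken off by markers. Its members differed among themselves: Cd163, a hemoglobin scavenger receptor, stood at 359 and 35.7 CPM (-3.32, -3.89 to -2.79) and Arg1 at 799 and 519 CPM (-0.63, -0.84 to -0.40), while Mrc1, the mannose receptor, stood at 285 and 383 CPM (0.42, 0.09 to 0.78) and Marco at 148 and 197 CPM (0.40, -0.05 to 0.92). Arg1 is also a urea cycle enzyme of hepatocytes. Hepatocyte markers in these cells stood at 72.8% of their hepatocyte level in the control library and 67.9% in the GS_KO library. How much of the Arg1 value is hepatocyte RNA was not tested. Cd274, the gene of PD-L1, had 0 and 82 UMIs and Trem2 stood at 53.7 and 18.8 CPM (-1.53), both chosen after the values were seen.

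Other lists in Kupffer cells were read at a minimum of 500 UMIs. These cells came from 3 clusters, shared unevenly: that led by Tmsb4x and H2-Aa held 226 control and 1062 GS_KO cells, that led by C1qa held 65 and 293, and that led by Ptprm and Zeb2, with no Kupffer marker among its 10 leading genes, held 146 and 248. Genes matching the ribosomal name pattern were higher in the GS_KO library (median 0.37; 71 higher, 13 lower; above all random lists), against -0.59 in hepatocytes. The lists below do not hold the mix of clusters equal between the libraries. MHC class II genes had a median of 2.80 (7 of 7 higher; 2.79 with the member at 0 set to 3 counts) and interferon response genes 1.42 (19 of 19), both above all random lists. MHC class I genes had one of 1.26 (9 of 9; percentile 99.99), inflammatory macrophage genes 0.98 (11 higher, 3 lower; 99.99), Kupffer identity genes 0.67 (14 and 3; 99.98), proliferation genes 1.12 (9 of 9 higher; 99.2) and lipid-associated macrophage genes -0.46 (3 and 7; 3.76), -0.25 with median of ratios scaling and -1.21 with free RNA taken off by markers, where Kupffer identity lay at 0.31. Interferon-induced genes were among those highest in the GS_KO library: Cxcl9 at 3.36 and 102 CPM (4.34, 2.41 to 10.24, with 1 control UMI), Gbp2b at 30.2 and 371 CPM (3.54, 2.68 to 4.75) and Ifi47 at 6.72 and 101 CPM (3.59, 2.02 to 6.97), beside Ly6a at 10.1 and 146 CPM (3.64). S100a9, a neutrophil and monocyte gene, had 0 and 117 UMIs, at least 10.4-fold higher. Hepatocyte lists differed in the same barcodes as in hepatocytes, with acute phase genes at 1.84 (above all random lists) and pericentral genes at -1.17 (below all), and 10 of the 15 highest and 12 of the 15 lowest genes had higher CPM in hepatocytes. The median over the 2881 genes with at least 20 UMIs in each library lay at -0.21 in these cells, and over the 266 such genes at a minimum of 1000 UMIs it lay at -0.48. At 1000 UMIs, the genes furthest apart were again mostly higher in hepatocytes (10 of the 15 highest and 9 of the 15 lowest), with H2-Aa at 206 and 2628 CPM (3.59, 2.68 to 4.89), Fcer1g at 51.5 and 583 CPM (3.19, 1.61 to 6.57) and C1qc at 154 and 912 CPM (2.45, 1.41 to 4.03) among the others. Their control values rest on 8, 2 and 6 UMIs.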

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

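The tests in this part were chosen after the results were seen. Signals outside the cells were looked for in barcodes of 200 to under 400 UMIs, which lie under the cell minimum and are part of no cell class, although those under 300 UMIs give the free RNA profile. Of 573 genes in the lists, 8 had at least 100 CPM in the GS_KO library and at least 16 times the control level there, limits that were set after the data were seen. They were Lcn2 at 2262 CPM (control 7.59; 298-fold), Saa1 at 5017 CPM (74.5; 67.3-fold), Saa2 at 1793 CPM (17.5; 102-fold), Saa3 at 940 CPM (11.7; 80.4-fold) and Orm2 at 1004 CPM (14.7; 68.4-fold) of the acute phase list, and Cd74 at 827 CPM (24.8; 33.4-fold), H2-Aa at 339 CPM (13.6; 25.02-fold) and H2-Ab1 at 163 CPM (6.23; 26.2-fold) of the MHC class II list.

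MHC class II genes were higher in the GS_KO library in hepatocyte barcodes, in Kupffer cells and in small barcodes, while macrophage lists went both ways in Kupffer cells. Free RNA could carry MHC class II transcripts into hepatocyte barcodes: over 7 MHC class II genes, the GS_KO hepatocyte level was a median of 0.293 times that of the small barcodes (members from 0.220 to 1.55). The free RNA share of these hepatocytes was put at 38.5% by 1 estimate and 22.9% by the other, so the median member is near what free RNA would bring, and Ciita, at 1.55, is above it. A larger amount of macrophage RNA with no change in its makeup would move MHC class II and C1q genes by the same factor. In small barcodes the MHC class II median of 4.64 (members from 3.45 to 6.40) lay 1.70 above the C1q median of 2.94 (2.64 to 2.94). Cd74 (4.97 to 5.15), H2-Aa (4.52 to 4.77) and H2-Ab1 (4.53 to 4.91) lay above the highest counting bound of C1q, 3.07. For these genes the values argue against it as the only cause. The lowest counting bound of a member, 2.63, lay under 3.07, so it stays open for the list as a whole. Other cells also make MHC class II, so a change within macrophages is not shown. With 1 mouse per group, an effect of Glul loss cannot be separated from a difference between the mice or their preparations, for which no test was possible.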

How the results depend on the processing

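No paired analysis was possible because each group is 1 library. The cell calling by 10% of the 99th percentile and the free RNA profile of barcodes under 100 UMIs were not run, and the mitochondrial settings removed no barcode and so say nothing about stability, though they are among the settings counted below. Depth limits single cells to a median of 1185 and 1208 UMIs in hepatocytes and classes other than hepatocytes to few counts. The cause of the differences below was not tested.

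Glul in hepatocytes stayed at -2.47 to -1.85 under 11 settings and moved to -0.91 at 2000 UMIs, -1.63 with free RNA off by genes of other classes ("by markers"), -3.53 in barcodes of 200 to under 400 UMIs ("small barcodes") and -3.03 over all barcodes. The pericentral median stayed at -0.81 to -0.58 under 14 settings, moved to -0.50 at 2000 UMIs and -0.95 in small barcodes, and reversed to 0.12 with free RNA off by markers. The periportal median stayed at -0.39 to -0.23 under 15 and moved to -1.15 at 2000 UMIs and -0.0807 with free RNA off by markers. The glutamine and glutamate median stayed at -0.52 to -0.43 under 11 and moved to -0.68 at 2000 UMIs, -0.33 and -0.35 with free RNA off by markers and by the median UMIs of barcodes ("by load"), -0.31 in small barcodes, -0.35 over all barcodes and -0.63 with members of at least 100 UMIs. The immunosuppressive median in Kupffer cells stayed at 0.03 to 0.68 under 13, reversed to -0.19 with members from 5 UMIs, and had no value at 2000 UMIs or with members of at least 100 UMIs. The macrophage share difference stayed at 34.4 to 39.3 points under 9 and was 0 at 2000 UMIs, which is no usable value: Kupffer was the only named class besides hepatocytes, and its 14 control cells held 4 Kupffer marker UMIs, all of Slc40a1. That setting left 19 and 33 hepatocytes. Of 33 list medians in hepatocytes, 15 kept their sign at 2000 UMIs, 4 changed it and the others had no value. With free RNA off by markers, 24 of the 28 with a value kept it, and at most 5 changed sign under any setting. Of 30 named genes, 24 to 30 kept theirs. With free RNA off by markers, Saa1, Saa2, Saa3 and Orm2 had 0 counts left in hepatocytes, and Cyp4a10 and Dbp had 0 in the control library and 2.47 and 1.23 in the GS_KO library, which puts their ratios at 2.17 and 1.38.

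Among genes with at least 3 counts left, these reversed in hepatocytes. At 2000 UMIs: Slc40a1 1.59, B2m -0.0325, Il18 -0.17, mt-Nd6 0.23, Rps6ka3 -0.91. At 500 UMIs: Otc -0.14. Free RNA off by markers: Hamp 0.88, Cebpb 1.25, Scd1 -0.0682, Mup17 4.09. By load: B2m -0.21. Small barcodes: Id3 -0.24, Gclc -0.13, Atf3 -0.23, Nr1d1 -0.91, Bdh1 -0.14, Mup10 -0.58, mt-Nd1 0.13, Sesn1 0.0320, Ahr -0.29, Otc -0.14. All barcodes: Id3 -0.10, Nr1d1 -0.70, Bdh1 -0.0456, Mup10 -0.42, mt-Nd1 0.0779, Ahr -0.0265, Otc -0.16. In Kupffer cells at 500 UMIs with free RNA off by markers: Saa2 -5.36, Saa3 -1.47, Mt1 4.83, Hamp 2.06, Oat 3.66, Cyp2e1 0.67, mt-Nd3 0.0628. By load: Saa2 -5.36, Saa3 -0.37, Fgb -9.41, Oat 0.53.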

Other observations

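All tests in this part but that on acute phase groups were chosen after the results were seen. LSEC and stellate cells could be read only at a minimum of 500 UMIs, and hepatocyte RNA runs through both. In LSECs, interferon response genes had a median log2 ratio of 1.31 (5 of 5 higher), MHC class I genes 1.37 (6 of 6), lipid-associated macrophage genes 1.60 (5 of 5) and LSEC identity genes 0.08 (4 higher, 4 lower). In stellate cells, interferon response genes had a median of 1.08 (7 of 7), MHC class II genes 4.17 (3 of 3) and stellate activation genes 0.77 (3 of 3). Free RNA, as set by markers, made up 70.4% of control and 64.4% of GS_KO LSEC UMIs, and 64.6% and 57.8% of stellate UMIs. In small barcodes the MHC class II median log2 ratio was 4.64. Free RNA could therefore bring MHC class II transcripts into stellate barcodes. Whether LSECs or stellate cells themselves make the transcripts of these lists was not tested. Lcn2, Saa1, Saa2 and Orm2 were among the highest genes and Fkbp5, Thrsp, Lpin1 and Alas1 among the lowest in both classes. Of the 5 highest and 5 lowest, 3 and 4 had higher CPM in hepatocytes than in LSECs, and 5 and 5 than in stellate cells. Acute phase genes stood at 1.96 and 1.78, and pericentral genes at -1.39 and -0.98.

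In barcodes of 200 to under 400 UMIs, cytotoxic effector genes had a median of 2.70 (6 of 6 higher), T cell inhibitory genes 1.64 (4 higher, 1 lower), stellate activation genes 1.54 (6 of 6), LSEC pericentral genes 0.57 (3 and 1), LSEC periportal genes -0.17 (2 and 2) and proliferation genes -0.12 (9 and 11). Which cells these transcripts came from was not tested.

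The pericentral list was lower in GS_KO hepatocytes. Capture of fewer pericentral hepatocytes stays open: the periportal median was -0.35 (-0.41 to -0.19), but its members went both ways and it lay within the central 95% of matched random lists. A fall along with the acute phase response may account for part of it: in GS_KO hepatocytes the pericentral median of the 20% of cells highest over the 20% lowest in acute phase score was -0.79 (-0.95 to -0.46), but the periportal median was 0.82 between the same cells, so the score may also rank zones, and in the control library the medians were 0.13 and 0.42. The score may also rank cells by depth or free RNA. The GS_KO cells highest in it held a median of 1146 UMIs and the lowest 1317. How much of the Saa and Orm2 RNA is in hepatocyte cells stays open, as given above. This comparison therefore cannot decide that explanation. Free RNA is undecided, with list medians of 0.12 (-0.18 to 0.33) and -0.58 (-0.82 to -0.39) under the 2 estimates of its share, and -0.74 with the first at a minimum of 500 UMIs. An effect of Glul loss itself was not tested apart from these.

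Clock genes differed in opposite directions in hepatocytes, with a night-phase median of 1.53 (1.26 to 1.92) and a day-phase median of -2.95 (-3.23 to -2.64). Livers taken at different clock phases could give this, which stays open: the day-phase median in Kupffer cells at 500 UMIs with free RNA taken off was -1.86 (-2.63 to -1.15), but hepatocyte nuclear genes were left at 77.7% of their hepatocyte level there. A change in Cre-targeted hepatocytes alone is undecided: the day-phase median in stellate cells at 500 UMIs with free RNA taken off was -2.87 over 9 members, but hepatocyte nuclear genes were left at 115% of their hepatocyte level there, so those cells do not read apart from hepatocytes.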
